A study of Arabidopsis thaliana and Oryza sativa and Zea mays with 54 samples.

How the data were processed

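The series compared ways of sequencing plant small RNAs that carry a modified terminal ribose at their 3′ end. It listed 54 samples in 32 groups of Arabidopsis thaliana, rice, maize and tomato. The values analysed here came from 1 library, replicate 2 of the group of AGO1-bound RNA from Col-0 inflorescences labelled high RI, prepared by terminal ribose-modified small RNA sequencing (TRM). All other samples, including replicate 1 of the same group, were not analysed here. In TRM, small RNAs were run through a denaturing gel that contained a boronate compound (PBA) and the excised RNA was then oxidised with periodate (NaIO4), per the labels' protocols. Both steps act on the free 2′ and 3′ hydroxyls of the last ribose, so RNAs with a modified last ribose are favoured. The RNA had been recovered by immunoprecipitation of AGO1, the main Argonaute protein that binds plant microRNAs, and libraries were made with an NEBNext small RNA kit, per the labels' protocols. Adapter ligation differs between RNA ends and was not measured in this library.

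The deposited values were raw counts, given per distinct sequence with no header, coordinates or gene names. Whether the sequences had been filtered before deposit is not given in the sources used here. The submitters' processing notes name Trim Galore 0.6.6, Bowtie, featureCounts and DESeq2, and the genome build TAIR10, without roles. The file listed 233160 distinct sequences of 18 to 28 nt, with 19362496 counts in all. All except 3 sequences, with 11 counts, matched the reference exactly, so tails added after transcription that differ from the genome could not be measured.

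Every sequence was matched without mismatches to both strands of the RefSeq assembly TAIR10.1, including the plastid and mitochondrial genomes, with code written in Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Coordinates are 1-based positions of these matches. In total 616807 genome positions were matched, and 73.9% of the sequences had 1 position. The matching was tested on simulated data. All 2000 sequences drawn from random positions were recovered at their origin. Of the sequences drawn from each of the miRNA, TAS, tRNA and rRNA genes, 200 of 200 were given their class. Of random sequences of the longest length listed, 0 of 200 matched. The drawn sequences were exact copies of the same reference, so the test checks the code only. Matches of shorter random sequences and the other classes were not tested.

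Each sequence was given to 1 RNA class, the first that any of its positions reached in a fixed order: miRNA hairpin on the sense strand, TAS locus on either strand, tRNA, rRNA, 45S flank, snoRNA, snRNA, protein-coding exon in sense, exon in antisense, intron, pseudogene, long noncoding and other noncoding RNA, and intergenic. A sequence had to lie wholly inside the gene. The 45S flank is the 4000 bases downstream of each annotated nuclear 5.8S gene, which hold the 25S rRNA that the annotation does not list. Reads antisense to miRNA, tRNA, rRNA, snoRNA and snRNA genes were counted with other noncoding RNAs, and pseudogene and intron reads were counted on both strands. The order and the flank were set after the leading sequences had been seen and before class shares were computed. Mitochondrial tRNA and rRNA genes, whose annotated type is "other", were moved to the tRNA and rRNA classes after class shares had first been computed. The comparison of 3′ ends, the 90% limit for arms, the TAS registers, the intergenic clusters and the chromosome 3 stretch were also chosen after seeing the data. The annotation holds 0 transposable element genes, so reads from transposable elements were counted in other classes, and the lists of transposable element genes and of AGO4-type loci had no members and gave no value. The plastid and mitochondrial lists took the genes of those 2 genomes.

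miRNA reads were summed per family over all hairpins, and each sequence was counted once per family. A gene's count leaves out reads given to an earlier class, such as those of a miRNA hairpin inside the gene, and includes reads shared with other genes of its class, so counts of near-identical loci are not independent, except for the counts per feature outside the miRNA, TAS, tRNA and rRNA genes, where shared reads were divided equally. A gene was called detected at 10 counts or more. tRNA positions were counted from 1 at the 5′ end of the gene. The tRNA anticodons are those of the annotation, which gives none for the plastid genes. The 3′ end of a miRNA was compared with the annotated mature end over the sequences that start at the annotated 5′ end, for matures with at least 1000 such reads, and matures with the same annotated sequence were treated as 1. For arms, a miRNA needed both a 5p and a 3p annotation and at least 10 counts in all.

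With 1 library there was no replicate error and no test across samples. Shares carry exact (Clopper-Pearson) 95% binomial intervals, computed with scipy 1.17.1, and a count of 0 allows up to 3 counts. Reads amplified by PCR without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Figures were drawn with matplotlib 3.10.9.

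Chosen before the data were examined were the results, the gene lists and the rule for named items: the 20 miRNA families with the highest counts, every TAS locus, the 5 tRNA groups with the highest counts and the highest locus of each, the 10 features with the highest counts outside these and the rRNA genes, and up to 5 members with at least 100 counts from each of the lists of AGO, biogenesis and miRNA target genes. Items named outside this rule, among them miR390, HEN1, CAB1 and the PPR genes, were chosen after their values were seen. For sequences, the 20 with the highest counts and the highest of each length were taken. Alternatives were the removal of rRNA, of organelle sequences or of the 10 features with the highest counts, merged families, the highest locus of each family, other count minimums, nuclear tRNA genes alone, list members with at least 1 read alone, and distinct sequences instead of reads. Tests between library types or genotypes, planned for a file with several libraries, were not run.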

Results

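The data describe small RNAs recovered with AGO1 from Arabidopsis inflorescences, in 1 library of 19362496 reads and 233160 distinct sequences. The preparation favours RNAs with a modified 3′-terminal ribose. The share of reads that passed this selection without a modification was not measured. No input or mock immunoprecipitate was analysed, so RNA carried along without binding AGO1 could not be told apart. AGO1-bound is used below for all RNA recovered in the immunoprecipitate. Replicate 1 of the group was not analysed, so each interval below is an exact 95% binomial interval that covers counting error only. The 20 most abundant sequences held 40.5% of all reads.

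The first question was which RNAs the selected AGO1-bound pool contained. microRNA hairpins gave 41.9% of the reads (41.87 to 41.92%) from 1082 sequences, and the TAS loci, which make trans-acting siRNAs, gave 3.55% (3.54 to 3.56%) from 866 sequences. Sequences outside annotated genes gave 27.4%, pseudogenes 8.74% and protein-coding genes 10.7%. The annotation lists no transposable element genes, so reads from transposable elements were not separated and would be counted in other classes, such as these. Only 61.1% of sense and 58.8% of antisense exon reads had 1 genome position, against 90.1% of intergenic reads. Exons come before pseudogene and intergenic in the class order, so the protein-coding share may be too high and the intergenic share too low. Reads with both a sense and an antisense exon position were counted as sense. tRNA fragments within the size range of the gel cut were rare, at 0.364% of the reads (0.362 to 0.367%). Annotated rRNA genes gave 0.935% (0.931 to 0.940%), with a further 1.47% from the 45S flank that holds the 25S rRNA. snoRNAs gave 0.0250% and snRNAs 0.0169%. Within protein-coding exons, antisense reads (5.14%) exceeded sense reads (4.10%), but by distinct sequences the direction turned, with 7.80% antisense and 8.65% sense. Introns gave 1.46% of reads. Long noncoding and other noncoding RNAs made up 4.90%. By distinct sequences the order differed: miRNA hairpins were 0.464% of the sequences, intergenic sequences 46.6% and pseudogenes 25.1%. Without the 10 features with the highest counts, all of them MIR319, MIR159 or MIR166 genes, the miRNA share fell to 23.8%.

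Reads of 21 nt formed 44.9% of the library, 22 nt reads 31.9%, 24 nt reads 11.7%, 20 nt reads 4.35% and 23 nt reads 3.92%. Uridine was the first base of 89.99% of the reads (89.98 to 90.01%), cytosine of 5.69%, adenine of 3.27% and guanine of 1.06%. AGO1 is known to prefer small RNAs that begin with uridine. The classes differed in both measures. miRNA reads were 66.2% 21 nt and began with uridine in 97.0% of cases, and TAS reads were 78.9% 21 nt with 96.1% uridine. Intergenic reads were 37.2% 22 nt and 26.7% 24 nt, with 88.2% uridine, and pseudogene reads were 42.2% 22 nt and 22.3% 24 nt. The 24 nt reads as a whole began with uridine in 96.3% of cases. tRNA fragments stood apart, with guanine first in 85.2% of reads and uridine in 9.30%. Among 26 nt reads, 64.9% came from tRNA genes. Counted over distinct sequences, 21 nt sequences were 27.1% and 22 nt sequences 28.2%, and without the miRNA hairpins 22 nt reads (35.1%) exceeded 21 nt reads (29.5%).

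**Figure D1:**
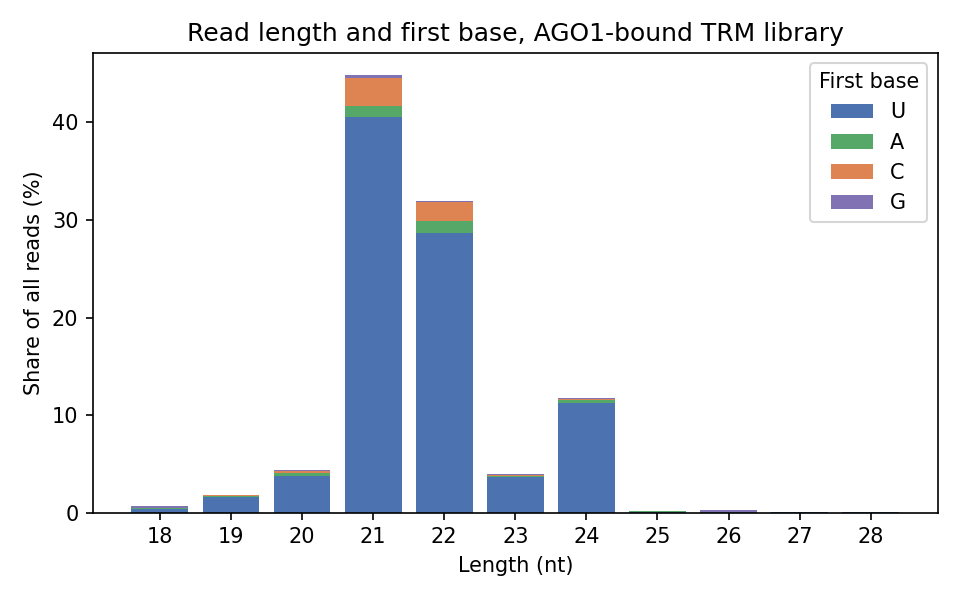
Share of all reads (%, vertical axis) by read length (nt, horizontal axis) in the AGO1-bound TRM library, with bars divided by the first base. Reads of 21 nt (44.9%) and 22 nt (31.9%) lead, followed by 24 nt (11.7%), and uridine is the most frequent first base at each length from 18 to 25 nt.

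The next question was which miRNA families gave the selected AGO1-bound reads. 3 families dominated: miR319, which targets TCP transcription factors, with 28.6% of the 8111852 miRNA reads (28.57 to 28.63%), miR159, which targets GAMYB-like MYB genes, with 26.05% (26.02 to 26.08%), and miR166, which targets HD-ZIP III genes, with 10.6% (10.59 to 10.63%). Together they held 65.3%, and the 20 leading families held 99.4%. Behind them came miR162 (8.69%), which targets DCL1, miR396 (7.08%), which targets growth-regulating factors, miR780 (3.76%), miR165 (3.13%), miR173 (2.78%), miR161 (2.63%), miR845 (2.40%) and miR158 (1.91%). The remaining 9 named families, miR831, miR395, miR163, miR156, miR403, miR447, miR168, miR167 and miR408, each held between 0.0440% and 0.555%. miR168, which targets AGO1 itself, had 5139 reads, and miR403, which targets AGO2, had 13819. Merging miR165 with miR166 gave 13.7% of miRNA reads. Of 326 annotated hairpins, 212 had at least 10 reads and 103 had none, while 162 had at least 10 reads that matched no other hairpin.

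The most abundant sequence of the library was the 22 nt TTGGACTGAAGGGAGCTCCTTC, with 1577908 reads or 8.15% of all, from the MIR319c hairpin (AT2G40805) on chromosome 2, 17029870 to 17029891, plus strand. The miR159b sequence TTTGGATTGAAGGGAGCTCTT followed with 1108054 reads (AT1G18075, chromosome 1, 6220813 to 6220833), then the miR159a sequence TTTGGATTGAAGGGAGCTCTA with 794714 reads (AT1G73687, chromosome 1, 27713234 to 27713254). The miR166 sequence TCGGACCAGGCTTCATTCCCC had 711601 reads and matched 7 hairpins, so its locus of origin is uncertain. miR162, as TCGATAAACCTCTGCATCCAG from 2 hairpins, had 561970 reads, and miR396b, as TTCCACAGCTTTCTTGAACTT on chromosome 5, 13611808 to 13611828, had 555469. The miR780 sequence TCTAGCAGCTGTTGAGCAGGT (AT4G14811) had 274063 reads, miR165 (TCGGACCAGGCTTCATCCCCC) 216005, miR161 (TGAAAGTGACTACATCGGGGT) 180252 and miR845a (CGGCTCTGATACCAATTGATG) 164841. For miR173, the arm that gave the reads was 3p: TCTGTGATTCTCTGTGTAAGC had 198001 reads and began 4 nt upstream of the annotated 3p start, while the 5p arm, the strand known to trigger TAS1 and TAS2 siRNAs, had 90 reads against 225032 for 3p.

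**Figure D2:**
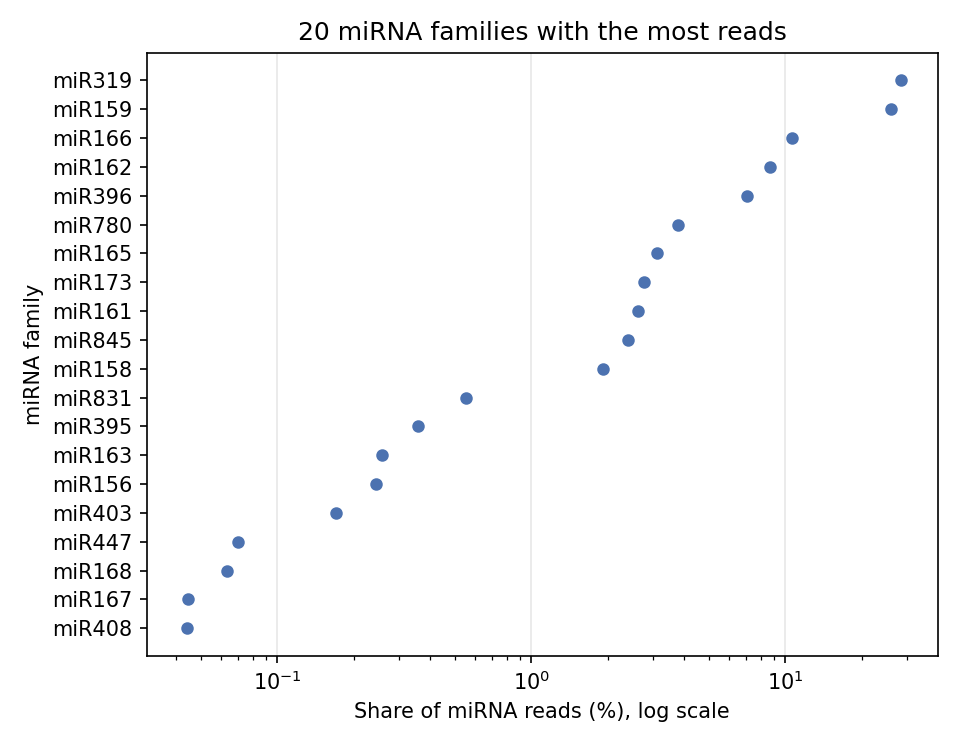
Share of miRNA reads (%, horizontal log axis) for the 20 families with the most reads (vertical axis). Points are shares and bars are exact 95% binomial intervals, narrower than the points. miR319 (28.6%) and miR159 (26.05%) lead, and miR408 is lowest at 0.0440%.

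Most miRNAs came from one arm. Of 67 miRNAs with both arms annotated and at least 10 reads, 51 had at least 90% of their reads on one arm, 31 had more 5p reads and 36 more 3p reads. Hairpins that share reads were counted separately here, such as miR398b and miR398c with 2058 reads each, so the 67 are not independent. miR396a was among those less one-sided, with 83.9% on 5p, and miR168a had 60.8% on 5p. Of the 11437 miR396a 5p reads, only 40.1% matched no other mature sequence, so the 5p share of miR396a is uncertain. miR390a, the miRNA that AGO7 binds to trigger TAS3, had 44.1% on 5p. Of the 5013 reads of the MIR168a hairpin, only 2547 matched no other hairpin, and miR168b had 2466 reads on 5p. For MIR390a, 448 of 1244 reads matched no other hairpin. The 5p shares of miR168a and miR390a are thus uncertain too, and the leading arm of miR168a may differ.

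3′ ends were then compared with the annotated mature ends, since the study concerned 3′ modification. Of 36 mature sequences with at least 1000 reads at the annotated 5′ end, 27 kept the annotated 3′ end in most reads, 7 were mostly shorter and 2 mostly longer. Among the 33 with most reads matching no other mature sequence, these numbers were 27, 4 and 2. The median share at the annotated end was 85.5%. miR319c was nearly always 1 nt longer than annotated, in 98.99% of reads (98.97 to 99.00%), and miR403-3p in 57.9%. miR319a, whose mature sequence is shared with miR319b, ended as annotated in 59.3% of reads and was 1 nt longer in 39.0%. The 1 nt longer form had 98271 reads for miR166, against 711601 at the annotated end, and made up 11.7% for miR162. miR158a-3p was split between its annotated 20 nt form, with 74207 reads, and a form 1 nt shorter, with 72068 reads, so that 49.3% of its reads were shorter (49.0 to 49.6%). miR162 had a form 2 nt shorter with 57365 reads (8.16%) but only 0.173% in the form 1 nt shorter. miR159b and miR159a share the 20 nt sequence TTTGGATTGAAGGGAGCTCT (121912 reads), so their shorter shares of 10.2% and 14.3% cannot be assigned to one gene. Reads of miR159c (86.9% shorter) are likewise shared in part, with 59.6% matching no other mature sequence. miR396b (98.0%), miR780.1 (99.2%), miR161.1 (99.2%) and miR845a (99.7%) ended almost entirely as annotated. All longer and shorter forms named here match the genome.

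**Figure D3:**
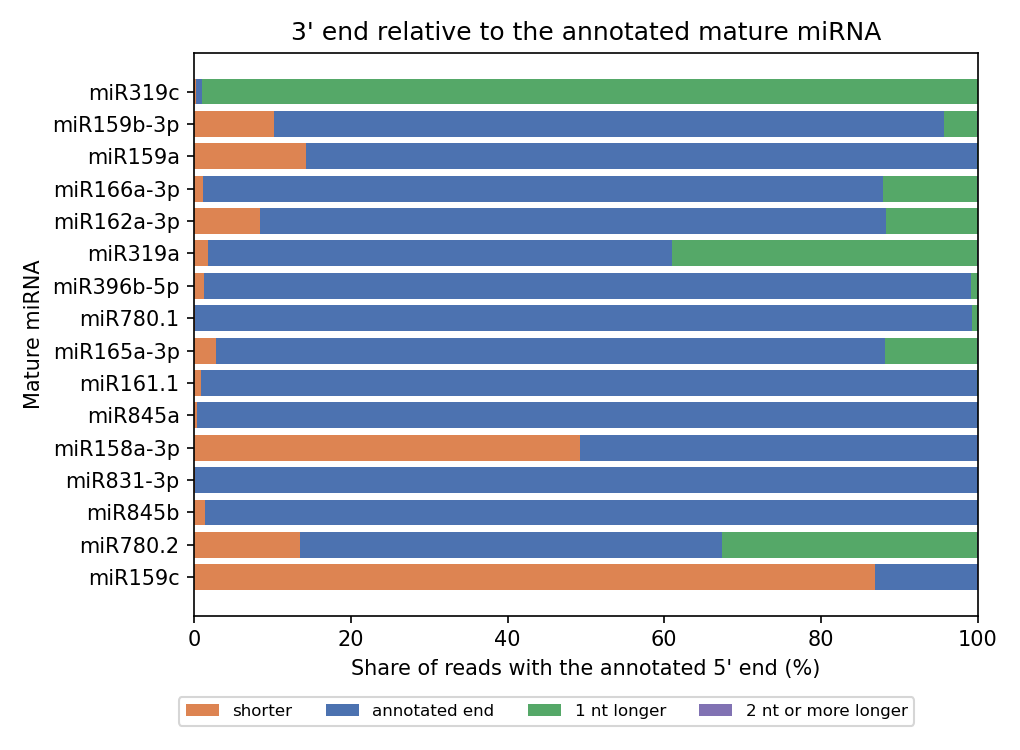
Share of reads with the annotated 5′ end (%, horizontal axis) by 3′ end class, for the 16 mature miRNAs (vertical axis) with the most reads among those where over 50% of reads start at the annotated 5′ end. miR319c is almost all 1 nt longer (98.99%), miR158a-3p is split between shorter (49.3%) and annotated (50.7%), and miR845a is almost all annotated (99.7%).

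Trans-acting siRNAs came mainly from 1 locus. TAS1C (AT2G39675, chromosome 2, 16537288 to 16538277) gave 60.1% of the 686777 TAS reads (60.0 to 60.2%), and its sense sequence TCGGTGGATCTTAGAAAATTA alone had 262399 reads. TAS3B (AT5G49615) gave 11.4%, TAS2 (AT2G39681) 10.96%, TAS1B (AT1G50055) 9.27%, TAS1A (AT2G27400) 5.48%, TAS3A (AT3G17185) 2.55% and TAS3C (AT5G57735) 0.275%. TAS4 (AT3G25795) had 28 reads from 2 sequences. Strands differed between loci: TAS3B reads were 99.6% sense, TAS1A 92.6%, TAS3A 89.2%, TAS2 74.2% and TAS1C 67.6%, while TAS1B reads were 98.3% antisense and TAS3C 76.6% antisense. TAS3B and TAS2 were richest in 22 nt reads, at 48.2% and 35.2%. The most abundant TAS3A sequence was TTCTTGACCTTGTAAGACCCC, with 5257 reads at 5862206 to 5862226 on chromosome 3. Of 21 possible registers of the 21 nt reads, the leading one held 90.6% of reads for TAS1A, 80.1% for TAS1B, 78.6% for TAS3C, 73.4% for TAS1C, 51.3% for TAS2, 50.6% for TAS3B and 43.1% for TAS3A, where an even spread would give 4.76%. In each of these loci 1 sequence gave most reads of that register, from 80.3% for TAS1A and 90.8% for TAS3A to 99.0% or more for the other 5. Over distinct 21 nt sequences the same register held from 4.92% for TAS1B to 16.3% for TAS1A, and the register was chosen as the highest of each locus.

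The study's title concerns modified small RNAs from tRNAs. Here 343 sequences and 70576 reads came from tRNA genes, and 1 group dominated. Nuclear tRNA-Gly (TCC) gave 65.5% of tRNA reads (65.2 to 65.9%), or 70.3% of those from nuclear tRNA genes alone. Its leading sequence, the 26 nt GCGTCTGTAGTCCAACGGTTAGGATA, had 37423 reads and matched 12 genes, one of them AT5G59395 on chromosome 5, 23957430 to 23957501. tRNA-Ser (AGA) gave 12.99%, mostly as the 18 nt GTGGACGTGCCGGAGTGG with 7756 reads, shared by 29 genes such as AT3G02715 on chromosome 3. tRNA-Glu (TTC) gave 4.38%, led by TCCGATGTCGTCCAGCGGTTAGGATA with 1379 reads (AT5G66755 on chromosome 5), tRNA-Ala (AGC) 3.20%, led by GGGGATGTAGCTCAGATG with 1284 reads (AT5G61445 on chromosome 5), and plastid tRNA-Gln 2.58%, led by TGGGGCGTAGCCAAGCGGTA with 778 reads at 6668 to 6687 of the plastid genome. Of 684 annotated tRNA genes, 441 had at least 10 reads, but identical copies share their reads, and at 100 reads the number was 173. Most tRNA reads began at position 1 (91.9%) and ended at position 26 (56.6%) or position 18 (16.2%). Position 26 was the end of 81.6% of tRNA-Gly (TCC) reads and 66.5% of tRNA-Glu (TTC) reads, and position 18 of 85.8% of tRNA-Ser (AGA) and 56.8% of tRNA-Ala (AGC) reads. 18 nt was also the shortest length listed and the lower limit of the gel cut. Ends before position 18 could thus not be seen for fragments that begin at position 1.

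**Figure D4:**
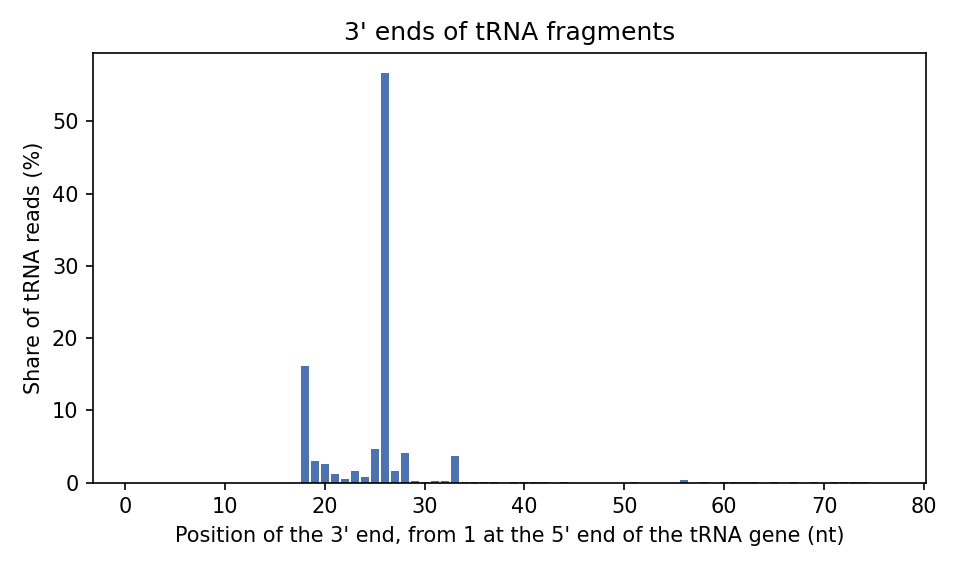
Share of tRNA reads (%, vertical axis) by the position of their 3′ end (nt, horizontal axis), counted from 1 at the 5′ end of the tRNA gene. Ends fall mainly at position 26 (56.6%) and position 18 (16.2%), and 18 nt is also the shortest read length listed.

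Outside the miRNA, TAS, tRNA and rRNA genes, 4 of the 10 features with the highest counts lay in one stretch of chromosome 3. They were AT3G06435 (protein-coding, 1968288 to 1970946) with 226114 reads, AT3G00220 with 86869, AT3G01845 with 84195 and AT3G01835 with 56139. The others were AT4G21366 (protein-coding, chromosome 4, 115712 reads, 84.1% of them 21 nt), the noncoding genes AT3G08370 (80843), AT3G05025 (76022) and AT3G07855 (56814), AT5G39370 (68436) and the pseudogene AT4G07031 (57800). AT4G07031 and AT3G07855 were rich in 24 nt reads, at 46.0% and 48.2%. Sense reads were the larger part for AT4G07031 (96.7%), AT3G01845 (95.9%), AT3G05025 (79.0%) and AT3G06435 (69.9%). They were the smaller part for AT5G39370 (20.6%), AT4G21366 (13.5%), AT3G01835 (10.2%), AT3G08370 (1.87%), AT3G07855 (1.67%) and AT3G00220 (1.59%). AT3G00220 on the plus strand overlaps AT3G01845 and AT3G01835 on the minus strand. Reads in these overlaps that are antisense to AT3G00220 are sense to the other gene, and the reverse, so the strand shares of these genes are not independent.

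Small RNAs also came from genes of the small RNA pathway itself. AGO genes gave 1118 reads, led by AGO1 with 892 and AGO2 with 120, and 5 of 10 had at least 1 read, with a median of 0.5. Biogenesis genes gave 445 reads, of which DCL1 had 358, without the 763 reads of the MIR838 hairpin that lies inside DCL1, and HEN1, the small RNA methyltransferase, 28, with a median of 2. Of all 27569 protein-coding genes, 9775 had at least 1 read and the median was 0. The 24 genes on the list of miRNA targets gave 6905 reads in all, 0.0357% of the library, with a median of 127. The list also holds ARF3 and ARF4, which are targets of TAS3 siRNAs rather than of a miRNA. The highest were AFB3 (1414 reads, 40.7% sense) and AFB2 (1204, 44.2% sense), auxin receptors targeted by miR393, then ARF4 (1099, 28.9% sense), TCP4 (1001) and AP2 (374). 14 of the 24 had at least 100 reads. Of the 13 listed pentatricopeptide repeat (PPR) genes, known sources of secondary siRNAs, 12 had at least 100 reads, and their union came to 109127 reads or 0.564% of the library. AT1G63400 had 99650 reads (12.2% sense), AT1G62914 94571 (8.81% sense) and AT1G63080 94082 (8.41% sense), and these overlap, since the union of all 13 genes was 109127 reads.

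By list, 20 conserved families, listed beforehand as families whose main strand begins with uridine, gave 35.6% of all reads, with a median of 3587 reads. In this library the leading sequence began with uridine in 16 of the 20, with cytosine in miR395, and with adenine in miR408, miR160 and miR393. The 40 families listed as Brassicaceae families gave 4.34%, with 31 of 40 at 10 reads or more. That list does not hold miR780 or miR831, and how well it covers the lineage was not checked. The list of miR169, miR172 and miR390 gave 1387 reads, 0.00716% of the library, of which 1303 were miR390. In this library the leading sequence began with uridine in 1 of these 3, miR169, and with another base in miR172 and miR390. The list also does not hold every family led by another base, since the leading miR845 sequence begins with cytosine. miR165 and miR166, which AGO10 also binds, gave 5.76%. The nutrient families gave 0.180%, with no reads for miR397, miR827 or miR857, and the 3 families of long DCL4-made hairpins gave 2560 reads. Among lists of RNA of other origin, the genes of abundant mRNAs gave 779 reads, of which CAB1 had 605. Only 8.43% of the CAB1 reads were sense and 76.9% were 21 nt, so most were not fragments of its mRNA. Plastid genes gave 42623 reads (0.220%) and mitochondrial genes 12423 (0.0642%).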

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

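No paired analysis was possible because the file holds 1 library, and the planned comparisons between library types or genotypes, with their normalization, filter, tool and left-out replicate alternatives, were not run for the same reason. Leaving out the 10 highest sequences, dividing reads over genome positions, class shares by distinct sequence, leaving out miRNA hairpins, list medians at 10 counts or more and the antisense share of exon reads were chosen after seeing the data. With 19362496 reads the counting intervals are so narrow that small shifts leave them, while rare items such as TAS4 rest on few reads. Distinct sequences peaked at 13 reads each; if that stands for 1 molecule, which is a hypothesis, intervals widen 3.61 times, 5 of the 22 class shares that moved lie within them, and the limit of 10 counts for a detected gene may be about 1 molecule. Without rRNA genes and the 45S flank, miRNA hairpins gave 42.9%, TAS loci 3.63% and tRNA 0.373%. Without sequences that match an organelle genome, the shares were 42.1% for miRNA, 3.56% for TAS, 0.341% for tRNA and 0.757% for rRNA. Without the 10 features with the highest counts they were 23.8%, 4.65%, 0.478% and 1.23%, and without the 10 highest sequences 14.7%, 3.29%, 0.548% and 1.41%, a fall of the miRNA share that follows from removing miRNA reads. With reads divided over positions, miRNA was 41.87%, TAS 3.54% and rRNA 0.928%. By distinct sequence they were 0.464%, 0.371%, 0.147% for tRNA and 1.56% for rRNA. With the highest locus of each family alone, miR319 held 25.1%, miR159 19.95% and miR166 12.5%, and merged with miR165 miR166 held 13.7%. Detected miRNA genes were 136 at 100 counts, and tRNA genes 285 at 50 counts and 173 at 100. tRNA-Gly (TCC) was 70.3% of nuclear tRNA reads. Over members with at least 1 read, the list medians were 9174 for PPR, 61 for AGO and 13 for biogenesis genes, and over members with at least 10 counts 9174, 90.5 and 27. By distinct sequence, 21 nt was 27.1%, 22 nt 28.2%, 24 nt 18.8% and uridine first 77.2%; with at least 10 reads 45.2%, 32.02%, 11.6% and 90.2%; without miRNA hairpins 29.5%, 35.1%, 19.99% and 84.9%. The shares without a class, without leading sequences or with the highest locus of each family alone moved because reads were removed. For the others the cause was not tested. The order of miR319, miR159 and miR166 was the same under each of these family settings. For the other 17 named families, whose values are not given singly, the share rose in 18 of the settings tried, fell in 1 and stayed within its interval in 15. Antisense reads were 55.6% of protein-coding exon reads, 52.6% without the PPR genes and the protein-coding genes among the 10 leading features, and 47.4% by distinct sequence, which turns the direction.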

Other observations

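Chosen after the values were seen were the clusters and the chromosome 3 stretch described here, and the tests of a count minimum, of a preferred fragment length, of a 2′-O-modified residue and of snoRNA guides. The tests of amplification and of the lower length limit were written before their values were computed, but after related values had been seen, namely peaks by length and class and shares of 18 nt reads. Reads outside annotated genes formed 18990 clusters of uniquely matching sequences, and the 10 highest held 22.99% of the 5307625 intergenic reads. The highest, on chromosome 1 from 17641375 to 17641953, had 369109 reads, 1.91% of the library, and 99.2% of them came from the plus strand. Of these, 66.8% were 22 nt and 98.6% began with uridine. The next, on chromosome 1 from 4506465 to 4506955, had 293329 reads, almost all from the minus strand (0.0668% plus), led by TGCCTCCCTCTGAACTTCGCTC with 139564 reads. A cluster on chromosome 2 from 2866621 to 2867165 was instead 49.4% 24 nt and held the most abundant 24 nt sequence, TTCGTGTCTTGTGATCTCCCATGT, with 42969 reads. A cluster on chromosome 4 from 13902659 to 13903073 came from both strands, with 51.3% plus.

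On chromosome 3, the stretch from 1966225 to 1970946 that holds 4 of the 10 leading features gave 463098 reads, 2.39% of the library, from 1933 sequences. They were 68.5% 22 nt and 2.40% 24 nt, and 28.5% of the reads had 1 genome position. Reads with several positions were counted here when the first position listed for their class lay in the stretch, so its total is uncertain, and 40.01% of the reads came from the plus strand by that position.

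The number of reads per distinct sequence fell from 17926 sequences with 1 read to 7097 with 5, then rose to a peak of 8456 sequences at 13 reads. A count minimum set by the authors is argued against by the 17926 sequences with 1 read. Amplification of few molecules by PCR may give such a peak, and then it should not depend on how many genome positions a sequence has. The peak lay at 12 reads both for sequences with 1 position and for those with at least 10, a ratio of 1, and at 11 to 14 reads for lengths of 19 to 24 nt, but at 6 in introns. No biological explanation was tested.

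tRNA fragments ended at position 26 or 18 in 72.8% of reads. The lower length limit of the library, where the labels place the gel cut at 18 nt, stays open as a reason for the 18 nt peak. Without the highest sequence of each length, the ratio of 18 to 19 nt reads was 3.36 in tRNA. In rRNA genes and their downstream flank together it was 0.880, so the tRNA ratio was 3.82 times higher. The fall from 18 to 19 nt was thus specific to tRNA in this comparison. It cannot decide the question, because tRNA fragments that end before position 18 were not listed and may have given the same ratio. A preferred fragment length stays open for position 26, since of 830 reads that began after position 1 in tRNA-Gly (TCC) and tRNA-Glu (TTC), 51.2% ended there (47.7 to 54.7%), and the groups differed, with 72.2% and 29.3%. It also stays open for position 18, where 0 such reads were listed because they would be shorter than the shortest length. A 2′-O-modified residue at these positions may be the reason, but it stays open too, because no conventional library was analysed here.

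Of 415347 rRNA read 3′ ends, 21.1% lay at 5 positions of the 6240 nt 45S stretch, and the others elsewhere in it. As a hypothesis, rRNA read ends may be residues whose 2′-O-methylation snoRNAs guide. Pairing of 11 nt between 295 annotated snoRNAs and the stretch predicted 67 sites, which held 0.179% of the ends, below the 1.07% of positions that are sites. All 24 shifts of the sites by up to 12 nt gave more, from 0.251 to 8.61%. The result argues against these predicted sites as the source of the ends, while sites that the pairing missed stay open, since it used 1 setting and was not compared with known sites.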
